A study of Mus musculus with 6 samples.

How the data were processed

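Memory-phenotype CD4+ T cells from the spinal cord (3 arrays) and the draining inguinal lymph nodes (3 arrays) of mice with acute EAE were compared. Per the labels' protocols, RNA was extracted with an RNeasy column kit and biotin-labelled cRNA was made by an Affymetrix amplification in 2 cycles from 1 ng of total RNA. Per the submitters' processing notes, the values came from RMA, which corrects background, normalizes arrays and summarises probes into probe sets; its version is not given in the sources used here. The deposited table held whole-number intensity values on a linear scale, from 9 to 39505, for 45101 probe sets, so log2 was taken before any test. No detection calls or genome build were used here, and no coordinates are given. Amplification in 2 cycles from so little RNA can add variation between arrays and shortens the 5' ends of the product.

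Samples were grouped by the tissue in their titles. The labels do not say how many animals stand behind an array or whether the arrays come from separate animals, so p-values measure the spread between these samples, which may be technical. No array's values were a copy of another's, since at least 93.6% of probe sets differed in value between any pair of arrays. This does not exclude arrays made from the same RNA. Signal over background cannot be judged array by array here, and the number of arrays limits the precision.

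Gene names came from the platform annotation. Of the probe sets, 34958 had 1 symbol, 932 had several and 9160 that were not controls had none; 64 were controls. By gene identifier 34754 of those with 1 symbol matched the mouse RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 symbols changed. Probe sets with several symbols were not used. For each of 18193 genes the probe set with the highest mean over the 6 arrays was taken. Of 266 called genes with further probe sets, 70 had another of opposite sign, 0 had another called in the opposite direction and 200 had no other called.

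Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on log2 values with tissue as the only term, two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p below 0.05. The 35 gene lists, 24 of T cell biology or identity and 11 of other cell types, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were alternatives; none of the 15 calls held with the estimated correlation. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. Of 536 listed genes 484 were measured, and 52 were not analysed here. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

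The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Dgat1, the 12 largest increases and 12 largest decreases among called genes whose groups did not overlap, up to 4 members of each list by adjusted p (by p where none was called), and a set of helper, regulatory, homing, identity and retinoid genes. The alternatives were a replicate block, each array left out, a filter on dim genes at the 40th percentile, median centring, quantile normalization, another variance model, array weights, other choices of probe set, stricter thresholds and a floor at the 20th percentile. Where the mean of the dimmer tissue lay below that floor, the fold of a called gene among the largest changes is given against the floor as a lower bound. Alternatives chosen after seeing the data left out both arrays of a number under the block, added the 5' to 3' actin signal or the macrophage list mean as a covariate, and used the second Dgat1 probe set.

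The sample titles number the arrays 1 to 3 in each tissue without saying what a number shares. Deviations from the tissue means, correlated across genes, were 0.576, 0.509 and 0.777 between arrays of the same number and -0.569 to 0.00506 between other arrays of different tissues, where genes are not independent. Centring on the tissue means makes an array's covariances with the arrays of the other tissue cancel, so part of this contrast is built in. From the positive values the numbers were taken to pair the arrays, a pairing that rests on the data and not on the labels.

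The fit was tested on simulated data of 18193 genes, with 50 genes changed at each of 4 sizes. With replicate-number effects simulated, the fit with tissue alone recovered 6% of genes changed by 1 on the log2 scale, 78% at 2, 90% at 3 and 96% at 4, with 0 false calls, and the block recovered 96% at 1 and 100% at each larger size, with 19 false calls. Without such effects the fit with tissue alone recovered 36%, 82%, 100% and 98%, with 5 false calls, and the block recovered 0%, 76%, 90% and 96%, with 2 false calls. Camera recovered 10 of 10 shifted lists and called 0 of 10 unshifted lists, which held random genes simulated without correlation. That simulation cannot show how often camera calls unshifted lists of correlated genes, and the macrophage list had an estimated correlation of 0.577.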

Results

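Gene expression was measured on microarrays in CD4+ T cells of memory phenotype taken from mice with acute experimental autoimmune encephalomyelitis (EAE), a model of inflammatory demyelination induced here with a peptide of myelin oligodendrocyte glycoprotein. The cells came from the spinal cord, the inflamed target tissue (3 arrays), and from the draining inguinal lymph nodes (3 arrays) of female C57BL/6 mice aged 8 to 10 weeks. The comparison asks which transcripts differ between T cells in the target tissue and T cells in the node that drains the immunisation site, and the series title names Dgat1. The 6 arrays had median intensities between 68 and 71. Arrays have no read depth, and their number, n = 3 per tissue, limits the precision of every value below. Fold changes are spinal cord over lymph node, with the standard error (SE) on the log2 scale.

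Among the largest differences, 3 cytokine genes were higher in the spinal cord samples and the follicular receptor gene Cxcr5 was lower. Ifng, the cytokine of type 1 helper cells, was 34.6-fold higher (log2 change 5.11 ± 0.44 SE), Il17a 20.8-fold (4.38 ± 0.59) and Csf2, which encodes GM-CSF, 18.5-fold (4.21 ± 0.30). Il17a read 6420, 2152 and 1378 in spinal cord arrays 1, 2 and 3, and without array 1 its log2 change was 3.75. The heat shock protein genes Hspa1a and Hspa1b were 79.0-fold and 30.5-fold higher. Cxcr5, the receptor that guides T cells to B cell follicles, was 48.0-fold lower in spinal cord (log2 change -5.58 ± 0.27), and the transcriptional regulators Pou2af1 and Id3 were 31.3-fold and 17.5-fold lower. Of 18193 genes, 206 were higher and 257 lower in spinal cord by limma with Benjamini-Hochberg adjustment, together 2.54%.

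**Figure D1:**
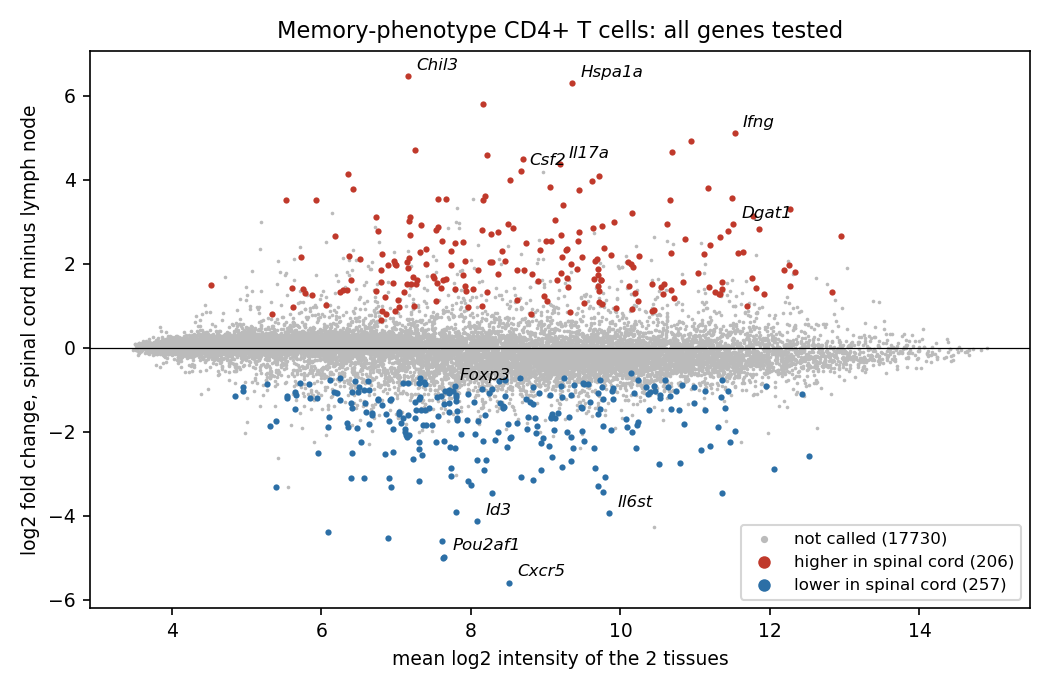
Mean log2 intensity of the 2 tissues (x axis) against the log2 fold change, spinal cord minus lymph node (y axis), for each of 18193 genes; red points are the 206 genes higher and blue points the 257 genes lower in spinal cord, and grey points were not called. The called genes lie across the intensity range, with Hspa1a at 6.30 and Cxcr5 at -5.58.

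The remaining genes among the 12 largest fitted increases were Chil3 (at least 54.0-fold), Lyz1 (55.7-fold), Klrb1b (26.4-fold), Plac8 (25.2-fold), Camk2n1 (24.3-fold), Gcnt2 (22.5-fold) and the neutrophil-attracting chemokine gene Cxcl2 (at least 13.7-fold). A fold written as at least was taken against the 20th percentile of all values, an intensity of 25, because the dimmer tissue lay below it. Chil3, a gene known from macrophages and other myeloid cells, and the lysozyme gene Lyz1 varied widely among the spinal cord arrays. Chil3 read 267, 5469 and 1684 in spinal cord arrays 1, 2 and 3 and 13 to 17 in lymph node. Lyz1 read 622, 6944 and 2281 in spinal cord and 28 to 68 in lymph node. Lyz2, of the macrophage list, read 245, 1771 and 563 in spinal cord, and whether the Lyz1 probe set also detects Lyz2 was not tested. Without spinal cord array 1 or 2 the log2 change was 7.64 or 5.46 for Chil3, 6.69 or 4.95 for Lyz1 and 4.74 or 3.42 for Cxcl2. Cxcl2 read 146, 908 and 304 in spinal cord. The list of macrophage, monocyte and microglia genes had a median log2 change of 1.23 (camera adjusted p = 6.96e-10, and adjusted p = 0.269 with an estimated correlation), with 0 of 20 members called by limma over all genes and 13 higher when adjusted over the list alone. The remaining genes among the 12 largest fitted decreases were Sostdc1 (32.0-fold lower), Ppic (24.3-fold), Afp (at least 22.6-fold), H2-Q2 (at least 12.5-fold), the cytokine receptor gene Il6st (15.2-fold), Ephx1 (10.8-fold), St8sia6, Nrn1 and Rflnb. The last 3 had log2 changes of -3.91 ± 0.48, -3.46 ± 0.31 and -3.46 ± 0.23. Another probe set of Afp had the opposite sign.

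All 463 called genes had tissue groups that did not overlap, and 18.5% of all genes did so, against 10% by chance for 6 exchangeable arrays. The arrays of one number deviated together, so that 10% is not the chance value of this design, and the other 3 splits that part all 3 pairs separated 2.19%, 2.34% and 5.06% of genes. The median called gene was 3.89-fold higher or 2.92-fold lower, and 190 of the higher and 216 of the lower genes differed by at least 2-fold. The first principal component held 44.9% of the variance and parted the tissues, and the second held 31.2%. The second ran with the replicate number, with scores of 35.4, 10.3 and -37.1 in spinal cord and 30.2, 4.4 and -43.1 in lymph node. The signal of poly-A control transcripts, added to the RNA, and the intensity of Dgat1 fell in the same order in each tissue. Whether this order is technical was not tested. With the replicate number as a block, 668 genes were higher and 1355 lower, and these held all 463. The counts also depended on single arrays: 136 genes were higher and 98 lower without spinal cord array 1, 49 and 32 without spinal cord array 2, and 119 and 95 without spinal cord array 3. They were 122 and 190 without lymph node array 1, 50 and 44 without lymph node array 2, and 109 and 148 without lymph node array 3. Of the 24 genes with the largest changes, 13 were called in each of these 6 fits, among them Hspa1a, Csf2, Cxcr5 and Pou2af1, while Chil3, Lyz1 and St8sia6 were called in 1 of the 6 (highest adjusted p 0.154, 0.149 and 0.0781). Ephx1 and Nrn1 were called in 4 fits (highest adjusted p 0.0757 and 0.0516) and Afp in 5 (0.0533). Ifng lost its call only without spinal cord array 2 (adjusted p = 0.0516) and Id3 only without lymph node array 2 (0.052), while Hspa1b was called in 4 of 6 fits (highest adjusted p 0.0516) and Il17a and Cxcl2 in 2 of 6 (highest 0.0926 and 0.14).

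Dgat1, which encodes an enzyme that makes triglycerides and can also esterify retinol, was 7.69-fold higher in the spinal cord samples. Its intensities were 13544, 7536 and 5158 in spinal cord arrays 1, 2 and 3 and 1588, 936 and 780 in the lymph node arrays of the same numbers. The log2 change was 2.94 ± 0.42 SE, from 12.98 ± 0.70 against 10.04 ± 0.53 (log2 mean ± SD, n = 3 each), with an adjusted p of 0.0274 by limma. A second probe set of Dgat1 was 15.6-fold higher (3.96 ± 0.67), with an adjusted p of 0.059 over probe sets. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow.

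The Dgat1 ratio within array pairs of one number was 8.53, 8.05 and 6.61, and with that number as a block the adjusted p was 0.000685. Leaving out single arrays gave log2 changes of 2.57 to 3.27, and the call was lost without spinal cord array 1 (adjusted p = 0.0559), spinal cord array 2 (0.115), lymph node array 2 (0.134) or lymph node array 3 (0.0892). Among alternatives chosen after seeing the data, covariates also ended the call. They were the 5' to 3' actin signal (log2 change 2.94 ± 0.46, adjusted p = 0.057) and the macrophage list mean (4.01 ± 0.64, adjusted p = 0.219). The macrophage list was itself higher in spinal cord, so its mean overlaps tissue. In the same group of alternatives, the call was lost with the block when both arrays of number 2 (2.91, adjusted p = 0.128) or of number 3 (3.05, adjusted p = 0.0942) were left out.

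The other genes of neutral lipid and retinyl ester synthesis did not move as a group. Of 16 measured members, Dgat1 and Plin2, a lipid droplet coat protein gene, rose (Plin2 2.79-fold, 1.48 ± 0.17), Acsl3, a long-chain acyl-CoA synthetase gene, fell by 1.90 on the log2 scale (SE 0.20), and 13 were not called. Adjusted over the list alone, 2 were higher and 2 lower, and the counts with the block over all genes were also 2 and 2. Dgat2, the other diacylglycerol acyltransferase gene, had a log2 change of 0.54 ± 0.22 (adjusted p = 0.338), and Lrat, the main retinol esterification enzyme gene, read 16 to 18 on every array. Without single arrays Plin2 was called in 3 of 6 fits (highest adjusted p 0.0717) and Acsl3 in 4 (0.0693). The list median was 0.03 (camera adjusted p = 0.725). In neutral lipid breakdown, Mgll alone of 10 members was higher (1.58-fold), also when adjusted over the list alone, and its call was lost whichever array was left out, with adjusted p from 0.107 to 0.182. That list had a median of 0.16 but a mean of -0.07, with camera pointing higher (adjusted p = 0.354), and with the block 1 member was higher and 2 were lower.

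Among 26 measured genes of retinoid metabolism and signalling, only Adh1, an alcohol dehydrogenase gene, was called. It fell by 1.60 on the log2 scale (SE 0.19, adjusted p = 0.0153), and it was the 1 member called when adjusted over the list alone. Without single arrays its call held in 1 of 6 fits. The retinaldehyde dehydrogenase genes Aldh1a1 and Aldh1a2 read 16 to 23 and 22 to 36, near the low end of the arrays. The retinoic acid receptor gene Rara had a log2 change of 0.04 ± 0.18 (adjusted p = 0.951). The list median was 0.07 and its mean -0.04, while camera pointed higher (adjusted p = 0.702). With the block, 1 member was higher and 2 were lower.

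**Figure D2:**
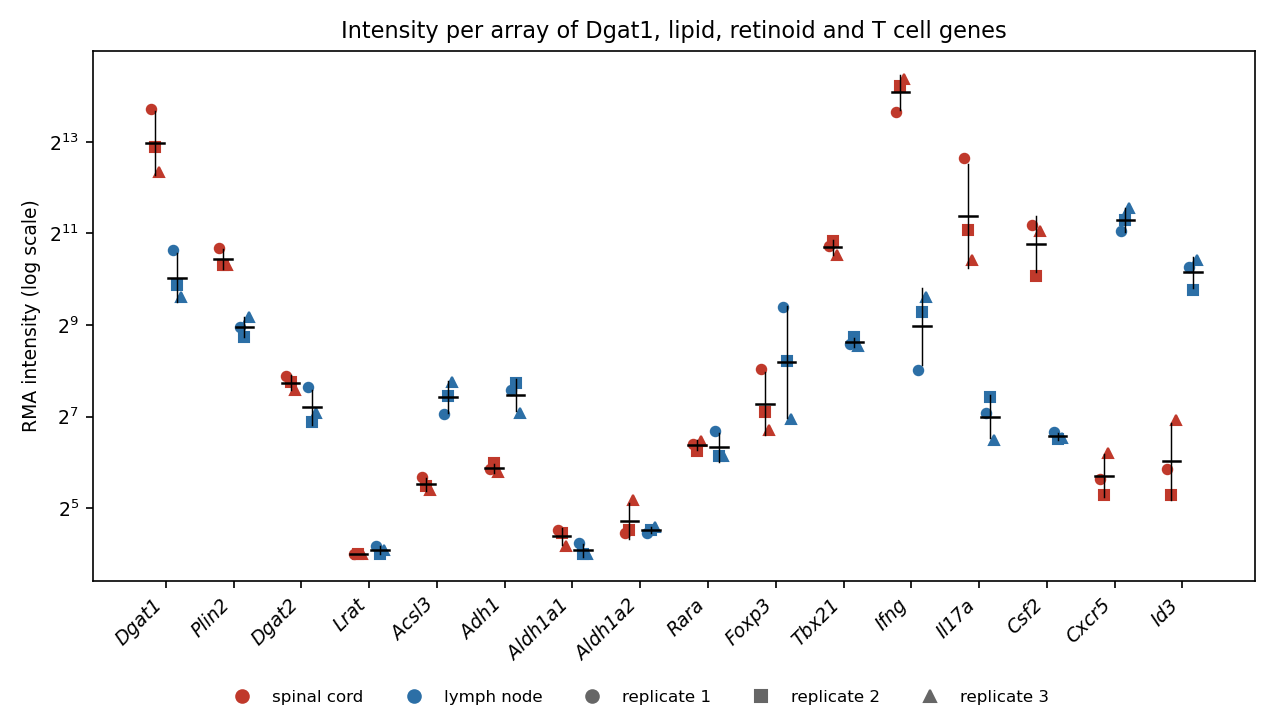
RMA intensity on a log scale (y axis) of 16 genes (x axis) on each of 6 arrays; red marks spinal cord, blue marks lymph node, the symbol shape gives the replicate number, horizontal bars are means of log2 values and vertical bars 1 SD (n = 3). Dgat1 lay between 5158 and 13544 in spinal cord and between 780 and 1588 in lymph node, while the tissues overlapped for Rara and Lrat.

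Type 1 helper genes were higher in spinal cord as a list, with 4 of 13 members called, and follicular helper genes were lower, with 7 of 14 called. The macrophage list (median 1.23) and the neutrophil list (1.31; 0.61 without spinal cord array 2) were higher in the same arrays. In the type 1 list all 13 measured members had positive changes (median 1.43), and Ifng, Tbx21 (the lineage transcription factor, 4.21-fold, 2.07 ± 0.13), Fasl (6.01-fold, 2.59 ± 0.28) and Tnf rose. Tnf read 3532, 1945 and 1682 in spinal cord and 774, 498 and 470 in lymph node. Adjusted over the list alone 9 were higher, and with the block over all genes the count was also 9, not always of the same genes. The list passed camera (adjusted p = 1.67e-10, and adjusted p = 0.129 with an estimated correlation). Without single arrays Tbx21 was called in all 6 fits and Fasl in 3 (highest adjusted p 0.0666), and Tnf lost its call whichever array was left out, with adjusted p from 0.0612 to 0.179. In the follicular list 7 of 14 members fell, with a median of -2.12, and 10 were lower when adjusted over the list alone. With the block 9 were lower and 1, the chemokine receptor gene Cxcr4, was higher (2.72-fold, adjusted p = 0.33; 0.00317 with the block). Those that fell included Cxcr5, the inhibitory receptor gene Btla (7.40-fold lower), Slamf6 (6.71-fold) and Cd200 (6.44-fold), while Bcl6, the follicular lineage factor, had a change of -0.50 ± 0.34 (adjusted p = 0.606). Camera gave an adjusted p of 2.22e-10, and the adjusted p = 0.101 with an estimated correlation. Without single arrays Btla was called in 5 of 6 fits (highest adjusted p 0.0501), Slamf6 in 4 (0.0543) and Cd200 in 2 (0.087).

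Of 12 cytokine genes linked to encephalitogenic T cells, Csf2, Ifng, Il17a and Tnf were the 4 called higher, 5 were higher when adjusted over the list alone, and the median was 0.81. The list passed camera (adjusted p = 9.96e-05), but not with an estimated correlation (adjusted p = 0.269 with an estimated correlation) or without members shared with other lists (0.0542). In the same arrays the macrophage list (median 1.23) and the neutrophil list (1.31; 0.61 without spinal cord array 2) were higher. The type 17 list went both ways: of 12 members Il17a rose, the chemokine receptor gene Ccr6 (3.72-fold lower) and Il21 (4.65-fold lower) fell, and 9 were not called. Adjusted over the list alone 4 were higher and 4 lower, and with the block 3 were higher and 4 lower. Its median was 0.20 and its mean -0.03, and camera pointed lower (adjusted p = 0.857). Without single arrays Ccr6 and Il21 were each called in 2 of 6 fits (highest adjusted p 0.111 and 0.145) and Il4, of the type 2 list, in 1 (0.144). In the type 2 list of 9, Il4 fell by 3.10 on the log2 scale (SE 0.49), also when adjusted over the list alone, and no other member was called; the median was 0.02, the mean -0.10 and camera pointed higher (adjusted p = 0.712). With the block 1 type 2 member was higher.

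Regulatory T cell genes split in direction. Foxp3, the lineage factor, read 264, 137 and 104 in spinal cord and 676, 299 and 123 in lymph node, a log2 change of -0.91 ± 0.66 that was not called (adjusted p = 0.64; 0.0641 with the block; exact permutation p = 0.3). Of 19 measured members, Fgl2 (14.1-fold), the interleukin-2 receptor gene Il2ra (2.17 ± 0.26 on the log2 scale) and the ectonucleotidase gene Entpd1 (3.09-fold) rose. Ikzf2, which encodes Helios (5.42-fold lower), Ebi3 (3.88-fold lower) and Izumo1r, which encodes folate receptor 4 (9.81-fold lower), fell. Adjusted over the list alone 6 were higher and 3 lower, and with the block 6 and 4. The median was 0.30 (camera adjusted p = 0.184). Without single arrays Fgl2 was called in all 6 fits, Ikzf2 in 5 (highest adjusted p 0.0513), Ebi3 in 3 (0.0781), and Il2ra, Entpd1 and Izumo1r in 2 each (0.09, 0.109 and 0.102). Entpd1 and Izumo1r lie outside the naming rule and were named after their values were seen, as were Bcl6, Cxcr4, Itga1, Egr2, Egr3, Cd79a and Ms4a1.

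The list of lymph node homing and quiescence genes was lower in spinal cord, and the inflammatory homing list was higher although its members moved both ways. The macrophage list, with a median of 1.23, was higher in the same arrays. In the first list 3 of 13 members fell, namely Ccr7, the receptor for lymph node entry (7.55-fold lower), Dapl1 (5.13-fold) and Klf3 (5.05-fold, with another probe set of opposite sign), and 5 were lower when adjusted over the list alone. With the block 7 were lower. The median was -0.92, or -0.46 without lymph node array 1 (camera adjusted p = 9.96e-05, and adjusted p = 0.269 with an estimated correlation). Each of the 3 was called in 1 of the 6 fits without a single array (highest adjusted p 0.101 to 0.161). In the second list of 21, Cd69, an early activation and tissue retention marker (3.63-fold), Ccr1 (6.48-fold) and the integrin gene Itga1 (2.63-fold) rose, while Gcnt1 (5.12-fold lower) and Ccr6 fell. Adjusted over the list alone 8 were higher and 2 lower, and with the block 9 and 2. The median was 0.31 (camera adjusted p = 0.00235, and adjusted p = 0.269 with an estimated correlation). It was 0.17 without spinal cord array 1, 0.60 without spinal cord array 3 or lymph node array 1, and 0.48 without lymph node array 3. Cd69 was called in 5 of the 6 fits (highest adjusted p 0.0543), Gcnt1 in 4 (0.0717), and Ccr1 and Itga1 in 1 each (both 0.161).

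The list of immediate early and activation genes was higher in spinal cord, with 6 of 24 members called, positive changes in 23 and a median of 1.23. Nr4a1 (7.08-fold, 2.82 ± 0.40), Nr4a2, Cd69 and Il2ra were among the 6 that rose, with Nr4a2 at 901, 1366 and 2568 in spinal cord and 59, 85 and 155 in lymph node, and 15 were higher when adjusted over the list alone. With the block 17 were higher. Egr2 and Egr3, which follow antigen receptor signals, had log2 changes of 0.12 ± 0.24 and 0.37 ± 0.29 and were not called. Camera gave an adjusted p of 7.79e-13, and the adjusted p = 0.129 with an estimated correlation. Without single arrays Nr4a2 was called in 3 of 6 fits (highest adjusted p 0.0962) and Nr4a1 in 1 (0.132). The macrophage list moved in the same direction, by a median of 1.23. In the list of heat shock and unfolded protein genes, Hspa1a and Hspa1b were the 2 of 16 that rose (3 adjusted over the list alone, 4 with the block), and the median was 0.25, or 0.13 without spinal cord array 1. Their camera adjusted p was 0.00041, and the adjusted p = 0.129 with an estimated correlation.

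Cytotoxic effector genes rose as a list, as the macrophage list did in the same arrays (median 1.23), led by Ctsw, a cathepsin of cytotoxic lymphocytes (3.81 ± 0.30 on the log2 scale), Fasl and Klrk1 (2.53-fold). These 3 of 13 members were called, 7 were higher and 1 lower when adjusted over the list alone, and 8 were higher and 1 lower with the block. The median was 1.27 (camera adjusted p = 1.11e-05, and adjusted p = 0.269 with an estimated correlation). Among 11 inhibitory receptors and related genes, Havcr2, which encodes Tim-3 (8.66-fold), Cd274, which encodes PD-L1 (1.92-fold), and Entpd1 rose, while Btla and Tox (6.33-fold lower) fell. Adjusted over the list alone 4 were higher and 2 lower, and with the block 5 were higher. The median was 0.44 (camera adjusted p = 0.116). Without single arrays Ctsw was called in all 6 fits, Tox in 5 (highest adjusted p 0.0516), and Havcr2 and Klrk1 in 4 (0.0516 and 0.0757), and Cd274 lost its call whichever array was left out, with adjusted p from 0.0534 to 0.0833.

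**Figure D3:**
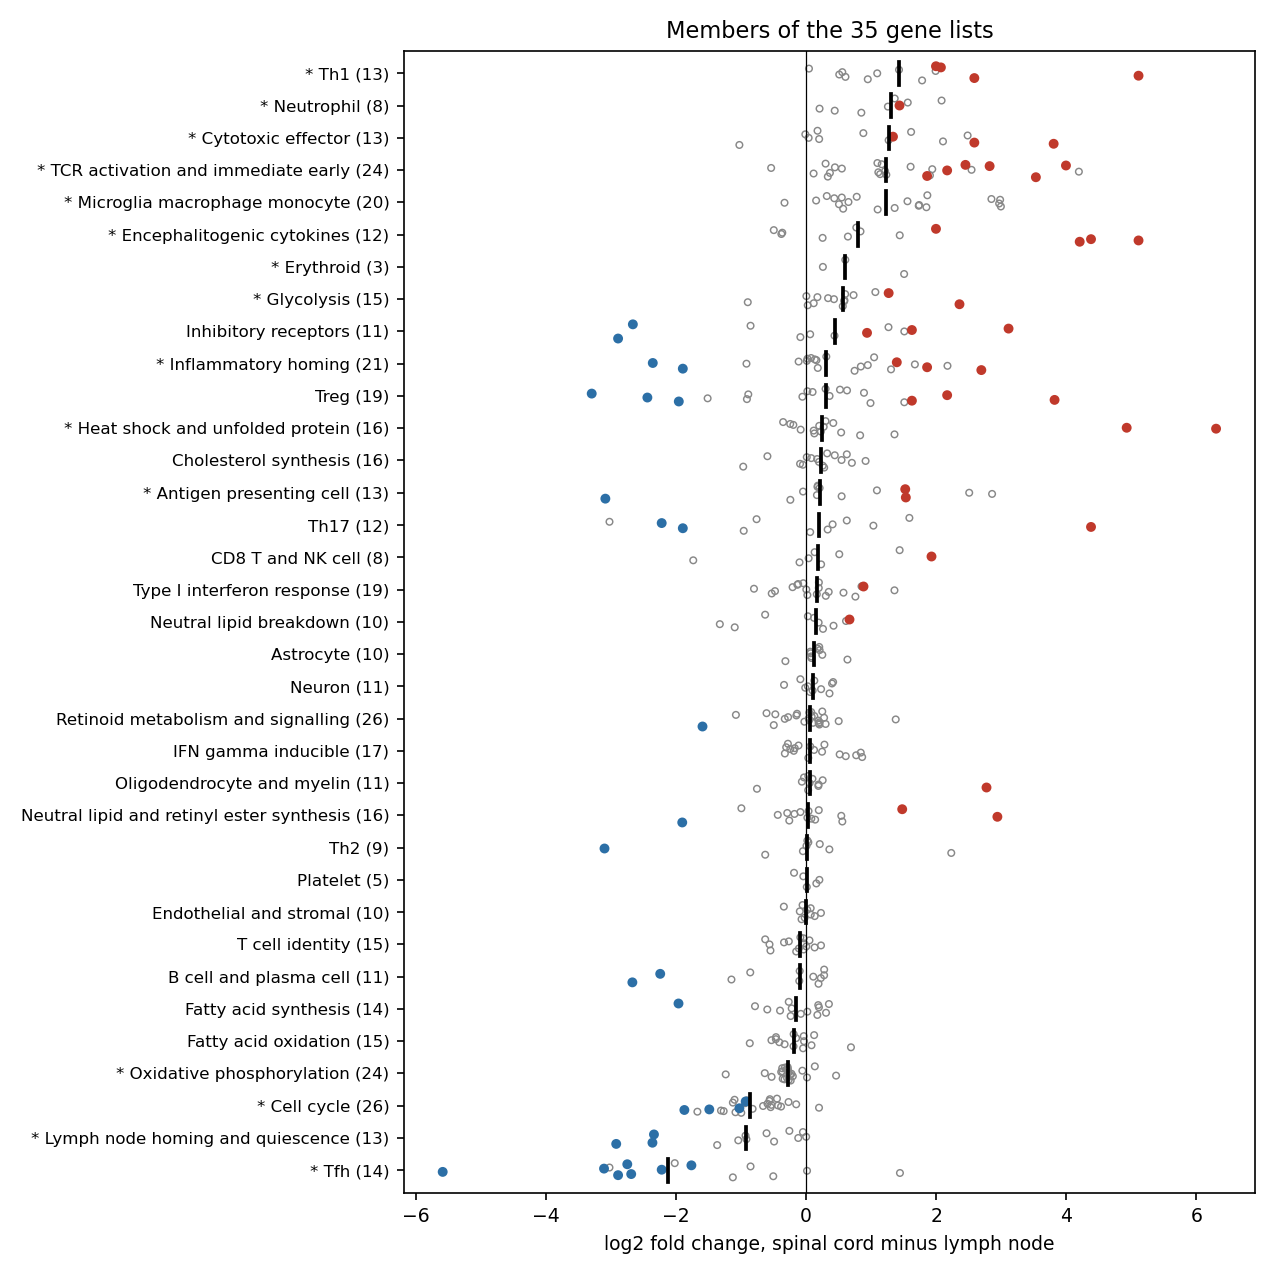
Log2 fold change, spinal cord minus lymph node (x axis), of the measured members of 35 gene lists (y axis, number measured in brackets); filled points are called genes, open points were not called, black bars are list medians and a star marks the 15 lists called by camera with its preset correlation. The type 1 helper list has a median of 1.43 and the follicular helper list of -2.12.

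The cell cycle list was lower in the spinal cord samples and the glycolysis list was higher. In the same arrays the macrophage list (median 1.23) and the neutrophil list (1.31, or 0.61 without spinal cord array 2) were higher too. Of 26 cell cycle genes 25 had negative changes, with a median of -0.86. Ccnb2 (3.65-fold lower), Cdc20 (2.80-fold), Cenpa (2.03-fold, with another probe set of opposite sign) and Plk1 (1.90-fold) fell, 8 were lower when adjusted over the list alone, and 17 were lower with the block. Camera gave an adjusted p of 3.28e-10, and the adjusted p = 0.269 with an estimated correlation. Without single arrays Cenpa was called in 2 of 6 fits and Cdc20 and Ccnb2 in 1 each (highest adjusted p 0.0746, 0.0771 and 0.12), and Plk1 in none, with adjusted p from 0.0762 to 0.113. Of 15 glycolysis genes, Hk2, a hexokinase (5.13-fold), and the glucose transporter gene Slc2a3 (2.41-fold) rose, 2 were higher and 1 lower when adjusted over the list alone, and the median was 0.57, or 0.37 without spinal cord array 1 and 0.28 without lymph node array 2. With the block 3 were higher and 1 lower. The list passed camera (adjusted p = 0.00107, and adjusted p = 0.269 with an estimated correlation). Hk2 was called in 3 of 6 fits without single arrays (highest adjusted p 0.0951). Slc2a3 lost its call whichever array was left out, with adjusted p from 0.0526 to 0.135.

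Oxidative phosphorylation genes were slightly lower as a list, with a median of -0.28 over 24 members and no member called over all genes or adjusted over the list alone. The median was -0.18 without spinal cord array 2 or lymph node array 3. In the same arrays the macrophage list (median 1.23) and the neutrophil list (1.31; 0.61 without spinal cord array 2) were higher. With the block 1 member was lower. The smallest p values belonged to Ndufs1 (-0.38 ± 0.14, adjusted p = 0.308) and Ndufb5 (-0.63 ± 0.25, adjusted p = 0.319), next to Sdha and Cox6c. The camera adjusted p was 0.0072, and the adjusted p = 0.36 with an estimated correlation. The list call was lost without spinal cord array 2 (adjusted p = 0.0608) or lymph node array 3 (0.144), after quantile normalization (0.0997) and among brighter genes alone (0.0677). In fatty acid synthesis Scd2, a desaturase gene, was the 1 of 14 members called, also when adjusted over the list alone (3.93-fold lower; list median -0.15, camera adjusted p = 0.541; 2 lower with the block). Scd2 was called in 1 of 6 fits without single arrays (highest adjusted p 0.165). No fatty acid oxidation gene of 15 was called over all genes or adjusted over the list alone, and Acadl had the smallest p (0.69 ± 0.20, adjusted p = 0.18; list median -0.19, camera adjusted p = 0.201). No cholesterol synthesis gene of 16 was called over all genes or adjusted over the list alone. Insig1 (0.92 ± 0.30, adjusted p = 0.235; 0.0274 with the block) and Pmvk (-0.59 ± 0.23, adjusted p = 0.315; 0.0348 with the block) were among the 2 higher and 2 lower with the block, where the list itself passed camera (median 0.23, adjusted p = 0.074; 0.0467 with the block). With an estimated correlation it had an adjusted p = 0.269, and 0.528 with the block. At the preset correlation that list also passed without spinal cord array 2 (adjusted p = 0.0287), lymph node array 2 (0.0193) or lymph node array 3 (0.0497), among brighter genes alone (0.0362) and after quantile normalization (0.00528).

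Interferon response genes moved little. Rsad2, an antiviral effector gene, was the 1 of 19 type I interferon genes that rose (1.84-fold; 2 adjusted over the list alone, 3 with the block), and it lost its call whichever array was left out, with adjusted p from 0.067 to 0.125. The median was 0.17 (camera adjusted p = 0.184). None of 17 interferon-gamma-inducible genes was called by limma, over all genes or adjusted over the list alone, against 3 with the block. Irf1 had a log2 change of 0.84 ± 0.21 (adjusted p = 0.12; 0.0381 with the block), Gbp7 of 0.77 ± 0.24 (0.205; 0.0332 with the block) and Gbp2 of 0.86 ± 0.24 (0.169). The median was 0.07 (camera adjusted p = 0.228).

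No T cell identity gene was called, and their list did not pass camera, while the macrophage list did with none of its genes called. None of 15 identity genes was called over all genes or adjusted over the list alone (median -0.09, camera adjusted p = 0.287). Cd247, which encodes the CD3 zeta chain, read 4085, 3345 and 3339 in spinal cord and 5083, 5005 and 5585 in lymph node, groups that did not overlap (-0.55 ± 0.13, adjusted p = 0.113). Cd4 had a log2 change of 0.23 ± 0.55 and Cd3e of 0.13 ± 0.26, and Trat1 (-0.63 ± 0.44, adjusted p = 0.626) was called with the block (0.0401). In the macrophage, monocyte and microglia list 19 of 20 genes had positive changes, with a median of 1.23. None was called over all genes, 13 were higher when adjusted over the list alone, and 9 were higher with the block. Csf1r read 237, 1486 and 754 in spinal cord arrays 1, 2 and 3 and 57 to 99 in lymph node (2.97 ± 0.67, adjusted p = 0.096; 0.0361 with the block). Lyz2 read 245, 1771 and 563 in spinal cord and 78 to 81 in lymph node (2.98 ± 0.68, adjusted p = 0.0983; 0.0212 with the block). Tyrobp (1.87 ± 0.39, adjusted p = 0.0782) and C1qb (adjusted p = 0.0519) were likewise called only with the block (0.0206 and 0.0119). C1qb read 42, 176 and 150 in spinal cord and 12 to 14 in lymph node, below the 20th percentile of all values, and against that floor it was at least 4.14-fold higher. The camera adjusted p of the list was 6.96e-10, and the adjusted p = 0.269 with an estimated correlation.

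**Figure D4:**
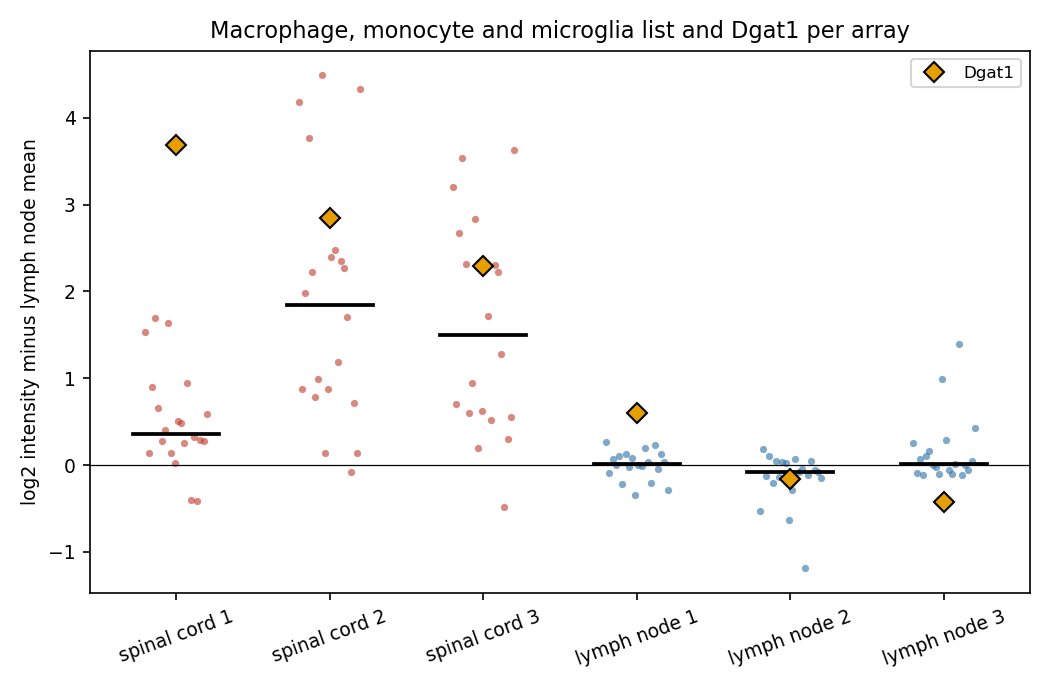
Log2 intensity minus the gene's lymph node mean (y axis) of the 20 measured macrophage, monocyte and microglia genes and of Dgat1 (diamonds) on each of 6 arrays (x axis); black bars are medians over the 20 genes. In spinal cord, 18 of the 20 genes were lowest on array 1, where Dgat1 was highest at 13544.

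Other myeloid and antigen-presenting genes were higher in spinal cord as lists. In the neutrophil list Mmp9, a matrix metalloproteinase gene, was the 1 of 8 genes called (2.68-fold; 2 adjusted over the list alone), with a median of 1.31, or 0.61 without spinal cord array 2 (camera adjusted p = 0.000156, and adjusted p = 0.269 with an estimated correlation). Mmp9 lost its call whichever array was left out, with adjusted p from 0.066 to 0.17. In the antigen-presenting cell list of 13, the costimulatory ligand gene Cd86 (2.90-fold) and Itgax (2.88-fold) rose and Cd83 (8.48-fold lower) fell, against 6 higher and 1 lower when adjusted over the list alone. The median was 0.21 (camera adjusted p = 0.000334, and adjusted p = 0.28 with an estimated correlation). Without single arrays Cd86, Itgax and Cd83 were each called in 4 of 6 fits (highest adjusted p 0.0543, 0.0625 and 0.0933). The 3 measured erythroid genes had a median of 0.60, or 0.32 without spinal cord array 1, with none called over all genes or adjusted over the list alone. Alas2 read 189, 40 and 48 in spinal cord and 21 to 30 in lymph node. The erythroid camera adjusted p was 0.0473, and the adjusted p = 0.269 with an estimated correlation; it was 0.142 without lymph node array 1, 0.0595 without lymph node array 3, 0.0718 after quantile normalization and 0.0507 without members shared between lists.

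B cell genes were not called as a list by camera, yet Cd22 (6.36-fold lower) and the immunoglobulin heavy chain gene Ighm (4.73-fold lower, with another probe set of opposite sign) fell. These were 2 of 11 members, and 3 were lower when adjusted over the list alone (median -0.10, camera adjusted p = 0.231; 0.00314 among brighter genes alone and 0.0323 by fry). Cd79a and Ms4a1 read 36 to 63 and 27 to 43 across all arrays. In the list of CD8 T and NK cell genes Klrd1 was the 1 of 8 called, also when adjusted over the list alone (3.80-fold; median 0.18, camera adjusted p = 0.074; 0.0362 without spinal cord array 1; 1 lower with the block). In the oligodendrocyte and myelin list Ermn was the 1 of 11 called, also when adjusted over the list alone (6.78-fold; median 0.06, camera adjusted p = 0.184; 0.0491 with the mean over probe sets; 1 lower with the block). Without single arrays Cd22 was called in all 6 fits, Ighm and Ermn in 4 (highest adjusted p 0.0728 and 0.0674) and Klrd1 in 1 (0.0964).

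The lists of other nervous tissue and stromal cells held no called gene over all genes or adjusted over the list alone. Astrocyte genes had a median of 0.13 over 10 members (camera adjusted p = 0.101), and Gfap, the astrocyte filament gene, had a change of 0.25 ± 0.14. Aldoc, an astrocyte-enriched aldolase gene (0.64 ± 0.30, adjusted p = 0.42), was called with the block (0.0229). Neuron genes had a median of 0.10 over 11 members (camera adjusted p = 0.172), with Stmn3 at 0.40 ± 0.14. Platelet genes had a median of 0.01 over 5 members (camera adjusted p = 0.712), with Gp9 at 0.16 ± 0.11. Endothelial and stromal genes had a median of -0.000444 and a mean of -0.00475 over 10 members, while camera pointed higher (adjusted p = 0.712), and Col3a1 had a change of 0.23 ± 0.15.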

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

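The tests of 5' to 3' signal, of handling and of other splits were chosen after the results were seen. So were those of array order for the macrophage list and of order within pairs. Rules for the sensitivity of spinal cord array 1 and for array order of stress genes were set before their own values were seen. Both rules single out the array where most macrophage genes were lowest, and neither held intervals. Among probe sets without a gene name, which no comparison uses, 29 were higher and 25 lower in spinal cord of 9160 tested with all probe sets. The poly-A control transcripts, which are added to the RNA and were not used in any comparison, differed 17.9-fold between the brightest and the dimmest array. Their signal was 6695, 847.5 and 373.6 in spinal cord arrays 1, 2 and 3 and 3766, 2474 and 737.5 in lymph node, while hybridisation controls differed 1.31-fold.

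Macrophage and neutrophil genes were higher in the spinal cord arrays of memory-phenotype CD4+ T cells, by a median log2 change of 1.23 for the macrophage list; limma called 0 of 20 macrophage and 1 of 8 neutrophil genes, and both lists had an adjusted p = 0.269 with an estimated correlation. Lower sensitivity of spinal cord array 1 as the whole account stays open. Of 195 other genes of like brightness that were at least 2-fold higher in spinal cord, 45.6% were lowest on array 1 (95% Wilson interval 38.8 to 52.7%), against 18 of 20 macrophage genes (69.9 to 97.2%). Within pairs the shares were 48.7% (41.8 to 55.7%) against 16 of 20 (58.4 to 91.9%). These intervals count genes as independent, while the macrophage list had an estimated correlation of 0.577. They are therefore too narrow, and their separation does not decide the question. Both shares of other genes lie above the 1 in 3 of 3 equal arrays, so lower sensitivity as a part of the pattern stays open as well. The count of 18 of 20, with list medians 1.23 and 1.08 higher on arrays 2 and 3 than on array 1, could come from RNA of myeloid cells in differing amounts. Among the macrophage genes Lyz2 reached 1771 and Csf1r 1486. No measured gene of the macrophage list stood in another list, and the labels do not state how the T cells were isolated, so expression by the T cells themselves and a difference of tissue, not tested, stay open.

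Dgat1 was 7.69-fold higher in spinal cord. RNA of myeloid cells as its source stays open: within pairs the log2 ratio of Dgat1 differed from that of pair 1 by -0.08 in pair 2 and -0.37 in pair 3 (95% interval ± 1.17 from the spread of 3 pair ratios), against macrophage list medians of 1.38 (95% interval 0.61 to 1.96) and 1.11 (0.26 to 1.52), and these intervals overlap. The list intervals count its genes as independent, so they are too narrow. A difference in 5' to 3' signal is argued against. The actin ratio was lower in spinal cord in 2 of 3 pairs and higher in the other, while Dgat1 was higher in all 3. With that ratio as a covariate the log2 change was 2.94 ± 0.46 SE against 2.94 ± 0.42 without it, and the adjusted p rose from 0.0274 to 0.057 in a fit with 1 residual degree of freedom fewer. A difference of tissue, other cell sources and effects of handling were not tested and stay open.

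Of 40 stress and immediate early genes 8 were called higher in spinal cord, and both lists had an adjusted p = 0.129 with an estimated correlation. RNA of myeloid cells as their source stays open. On spinal cord array 1, 11 of the 40, 27.5% (95% Wilson interval 16.1 to 42.8%), and 3 of the 8 called were lowest. The share met the bound set beforehand against this source, 1 in 3 or fewer, but its interval reached above that bound. That interval counts genes as independent, so it may be too narrow. Within pairs 21 of the 40 and 5 of the 8 were lowest in pair 1. There the macrophage list gave 16 of 20, and the 195 other genes set against that list gave 48.7%. Tissue handling before lysis and effects of the tissue itself cannot be told apart, because the labels do not describe the handling and any step that differed between the tissues would follow the groups: the immediate early list had a median log2 change of 1.226, which either could give.

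The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes, 1 split, the real one, reached 463 calls, and the highest of the others gave 0 by limma, with 41 to 2005 genes at an unadjusted p below 0.05 against 2599. For lists, 1 split reached 15 calls by camera, and the others gave 2 to 8. Of the 4 splits that part all 3 pairs, the other 3 gave 0 genes and 6 to 8 lists.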

How the results depend on the processing

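Alternatives with both arrays of a number left out, with covariates or with the second Dgat1 probe set were chosen after seeing the data. The counts of genes higher and lower (206 and 257) became 668 and 1355 with the replicate block, 56 and 47 at an adjusted p below 0.01, and 77 and 84 with a floor at the 20th percentile. Without single arrays they ranged from 49 to 136 and from 32 to 190, where fewer arrays were tested. With the block and both arrays of number 2 or of number 3 left out, limma called 0 and 0 (2985 and 2591 genes at an unadjusted p below 0.05). With the macrophage mean as a covariate it called 0 and 0 (1320 genes). The macrophage list was itself higher in spinal cord, so this covariate overlaps tissue. With it the SE of Dgat1 was 0.64, against 0.42 without it. The loss of calls therefore does not show that myeloid RNA accounts for them. With both arrays of number 1 left out the block gave 152 and 176, against 668 and 1355 with all arrays. All other counts stayed within 1.5 times of 206 and 257, from 142 to 258 higher and 198 to 342 lower. Dgat1 kept its direction in all alternatives, at 2.57 to 3.27 without single arrays. It lost its limma call without spinal cord array 1 (adjusted p = 0.0559) or 2 (0.115), or without lymph node array 2 (0.134) or 3 (0.0892). The call was also lost with the block and number 2 left out (2.91, adjusted p = 0.128) or number 3 left out (3.05, 0.0942). So it was with the actin covariate (2.94, 0.057), the macrophage covariate (4.01, 0.219) and the second probe set (3.96, 0.059). Over all alternatives its adjusted p ran from 0.000685 to 0.219. Lists higher and lower (11 and 4) became 0 and 0 by camera with an estimated correlation (6 lists at an unadjusted p below 0.05) and 4 higher with fry, which called type 1, cytokine, activation and heat shock lists higher and follicular, cell cycle and B cell lists lower. Of 1369 alternative values of 98 other called genes, 1085 kept the call, 284 lost it and 0 reversed; of 702 values of 51 uncalled genes, 19 gained one. Called lists kept 206 of 239 values, and uncalled lists gained a call in 10 of 320. Of 99 called genes named, Dgat1 included, 26 were called without any single array and 7 in no such fit. The sign differed for 28 values that stayed uncalled. Apart from the calls given beside results, the replicate block changed no other call by limma or preset camera among the genes and lists named. By fry the block ended the calls of the type 1 and B cell lists (adjusted p = 0.0567 for each). It brought calls of the lymph node homing (0.0328) and cytotoxic effector (0.00326) lists. Except where an alternative tests fewer arrays or genes, the cause was not tested. Median centring and quantile normalization shifted the median of all genes to -0.02 and 0.01. Genes near the floor, such as Lrat at 16 to 18, have little signal over background, which limits what their values show.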

Other observations

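The 12 largest fitted changes in each direction among called genes that the naming rule had not taken are given here, chosen after their values were seen. In spinal cord, the transcription factor genes Fosl2 (3.97 ± 0.48 on the log2 scale) and Atf3 (3.53 ± 0.51), the cell cycle inhibitor gene Cdkn1a (3.75 ± 0.17), the phosphatase gene Dusp5 (3.51 ± 0.27), the histone gene H1f2 (3.56 ± 0.23) and the chemokine genes Ccl1 (3.61 ± 0.55) and Cxcl3 (3.52 ± 0.15) were higher. So were AA467197 (4.09 ± 0.31), Pygl (3.78 ± 0.28), Sv2c (3.54 ± 0.33), Pkib (3.51 ± 0.34) and Gm36723 (3.51 ± 0.50). Cdkn1a read 2603, 2313 and 2738 in spinal cord and 157 to 225 in lymph node. Cxcl3 stayed dim, at 137 to 175 in spinal cord and 12 to 15 in lymph node. The dimmer tissue of Cxcl3, Pygl, Pkib and Itgb8 lay below the 20th percentile of all values, and against that floor they differed at least 6.26-fold, 12.7-fold, 8.21-fold and 5.29-fold.

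Lower in spinal cord were the costimulatory receptor gene Cd27 (-3.18 ± 0.34), the cholesterol transporter gene Abca1 (-3.13 ± 0.46), Izumo1r (-3.29 ± 0.43), Aff3 (-3.07 ± 0.31), the integrin gene Itgb8 (-3.32 ± 0.46), Ampd3 (-3.32 ± 0.59), Hmgn3 (-3.27 ± 0.29), Snn (-3.18 ± 0.29), H2-Ob (-3.09 ± 0.28), the potassium channel gene Kcna2 (-3.09 ± 0.22), Slc16a5 (-3.05 ± 0.28) and Synpo (-2.91 ± 0.44). All 24 had adjusted p between 0.00171 and 0.0492 by limma (n = 3 per tissue), and all but AA467197, Cdkn1a, Cxcl3, Dusp5, H1f2, Pygl, H2-Ob, Hmgn3 and Kcna2 lost the call without at least 1 array. The log2 change was -3.95 for Ampd3 without lymph node array 3, 4.14 for Atf3 without spinal cord array 1 and 2.96 for Ccl1 without spinal cord array 3.

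Gene families grouped by symbol stem, tried after seeing the data, gave no enrichment. In 632 one-sided Fisher exact tests over stems with at least 8 genes, 0 passed after adjustment. The smallest adjusted p was 0.119, shared by Ccr genes among those lower in spinal cord (3 of 10) and Cxcl genes among those higher (3 of 13).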
